A study of Mus musculus with 11 samples.

How the data were processed

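Messenger RNA levels were measured by RNA sequencing in pancreatic islets of 11 male mice aged 3 months. Per the labels' protocols, Arid1a was deleted by 10 mg tamoxifen per day for 2 days at 45 to 60 days of age in mice with floxed Arid1a and a ubiquitously expressed inducible Cre, and controls had floxed Arid1a without the Cre. The labels do not say whether controls received tamoxifen, so differences between genotypes may include its effect. Partial pancreatectomy (PPx), the surgical removal of part of the pancreas, was done 2 weeks later, and islets were taken 6 days after surgery. Per the labels' protocols, libraries were made with a Nugen Ovation kit and read as single 75 bp reads in 1 flow cell.

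The authors deposited 1 table of normalized read values, a signal that is never negative, with 1 column per library and gene symbols. Per the submitters' processing notes the tools were HISAT2, SAMtools, featureCounts and edgeR with the builds GRCm38 and mm10; versions, roles and the normalization are not given in the sources used here. In the 7 libraries with enough low values, at most 23.6% of these were whole multiples of a step, within a tolerance of 0.1. Whole reads were therefore not recovered and depth is unknown. The search took 1 step per library for all genes, so in a unit divided by gene length it would fail in any case. Over 343 single-transcript genes above 0 in 1 library, the value fell with transcript length (Spearman rho = -0.548, across genes, which are not independent replicates), so a length-normalized unit is possible. Of 20068 rows, 26 had a symbol turned into a date and were dropped, which left 20042 genes.

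All columns were divided by 1 common factor, 0.3763, for the tests alone, so that library totals kept their differences; the gene levels printed are the deposited values, not divided. Genes with a scaled value of at least 1 in at least 2 libraries were tested, 14738 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(scaled value + 1) with group means, an intensity trend in the variance and 1 estimate of the spread shared by all 11 libraries (7 residual degrees of freedom); effects over both states or genotypes came from an additive model. P-values were adjusted by Benjamini-Hochberg at a false discovery rate of 0.05. Fold changes are on the log2(scaled value + 1) scale, which understates the change of low genes. A gene at exactly 0 is called listed at 0, with no fold, since genes that every cell uses were also at 0. Fixed gene lists (30, of which 26 had enough tested members) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Replicates were separate mice; the comparisons share libraries and are not independent. No library duplicated another (highest r = 0.952).

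The test was tested on simulated data with 200 of 14738 genes changed, over 5 draws. With equal spread in all libraries, 5% of calls were false for KO vs control after PPx and 4.7% for PPx in KO. The spread was not equal: the root mean square SD within groups was 1.05 in KO after PPx, 0.7 in control without PPx, 0.57 in KO without PPx and 0.63 in control after PPx. With library spreads as estimated from the data, a mean of 134.4 of 263.6 calls (51%) were false for KO vs control after PPx, 398 of 544.2 (73.1%) for PPx in KO, 27.4 of 107 (25.6%) for the interaction and 49.6 of 206.2 (24.1%) for PPx over both genotypes. These shares hold for 200 changed genes and are no estimate for the real calls, whose number of changed genes is unknown. The fit with library weights, an alternative chosen before the data were examined, gave 5.5%, 6.6%, 6.4% and 4.2% in the same simulations. These drew library spreads from the weighted fit's own model, with genes varying independently and no scale difference. Its low share there was therefore built in and is no check on the real data. The planned fit was kept as the main one. In these comparisons "rose" and "fell" are written only of genes that also passed with library weights. This wording rule was chosen after seeing the data. Both fits kept the library totals as deposited, so passing both does not guard against a scale difference between libraries.

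Named genes were chosen by a rule fixed before the data were examined: Arid1a; the 8 highest and 8 lowest fold changes among called genes with separate groups and a mean scaled value of at least 5; up to 4 called members per list; where fewer than 5 genes passed, the 5 smallest p in each direction; and a fixed panel of 10 genes. Other pseudocounts, filters, scalings, variance models, library weights, fits of 2 groups and leaving out each library were tried as planned; 2 alternatives on transcript length, from a GENCODE annotation, were added after seeing the data.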

Results

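Normalized read values were measured in islets of 11 mice in 4 groups: 2 controls and 5 Arid1a knockouts (KO) without surgery, and 2 controls and 2 KO mice 6 days after partial pancreatectomy (PPx). Arid1a encodes a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The design addresses how loss of Arid1a alters islet gene expression at baseline and after loss of pancreas tissue. Sequencing depth was not given, so no counting interval could be set. The deposited values summed to 252739 and 277916 in the KO libraries after PPx and to between 344216 and 445674 in the other 9. The KO libraries after PPx also had fewer genes above 0 (11213 and 12948, against 13576 to 14857) and a smaller Ins2 share of the total (6.44% and 6.59%, against 20.2% to 32.3%). Gene levels below are the deposited normalized values. P-values of limma measure the spread between these mice, moderated towards a trend over genes of like level. Those of camera at the preset correlation compare the genes of a list with other genes and treat genes as nearly independent. They are therefore no measure of the spread between mice.

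**Figure D1:**
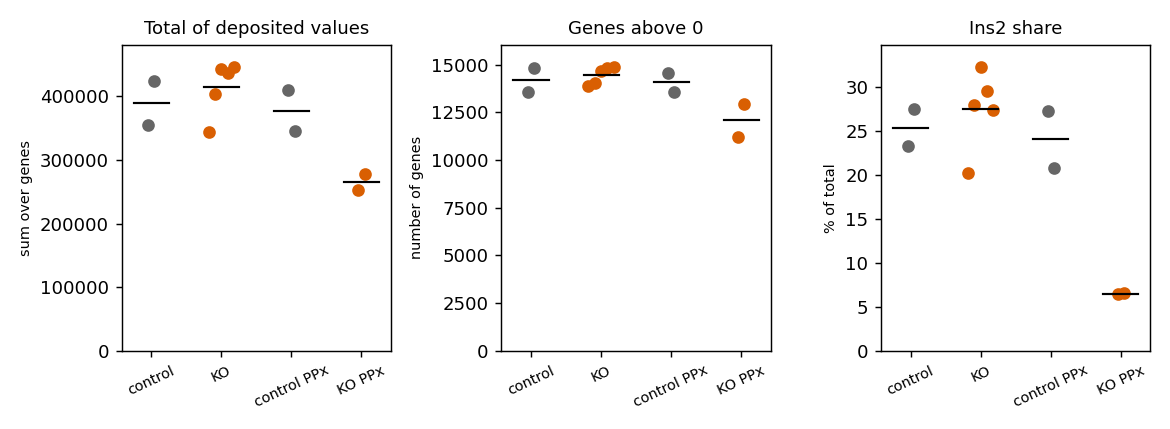
Each point is 1 library and each black line a group mean, for the total of the deposited values, the number of genes above 0 and the percent of the total taken by Ins2, by genotype and surgery. The 2 KO libraries after PPx lie lowest in all 3 panels, with totals of 252739 and 277916 and Ins2 shares of 6.44% and 6.59%.

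Arid1a itself (chromosome 4, 133679008 to 133756769, minus strand, GENCODE annotation of GRCm38) was only modestly lower in the libraries labelled KO and did not pass the test. Without PPx it was 30.9 ± 1.52 (SD, n = 2) in control and 24.9 ± 4.59 (SD, n = 5) in KO, a log2 fold change of -0.32 ± 0.19 (SE, limma, adjusted p = 1). One KO library, replicate 14, had 32.6, above both controls. After PPx it was 39.1 ± 4.44 (SD, n = 2) in control and 29.6 ± 4.45 (SD, n = 2) in KO, a log2 fold change of -0.40 ± 0.23 (SE, limma, adjusted p = 0.267), which turned to 0.11 with median-of-ratios scaling and 0.03 with the length trend removed. Removing the length trend also removed each library's level, and with transcripts of at least 2 kb alone the fold change stayed -0.40. A gene-level value also holds reads from exons outside a deleted part, so it checks the labels only weakly. The paralog Arid1b was 11.8 ± 1.55 (SD, n = 2) in control and 14.5 ± 1.54 (SD, n = 5) in KO without PPx.

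**Figure D2:**
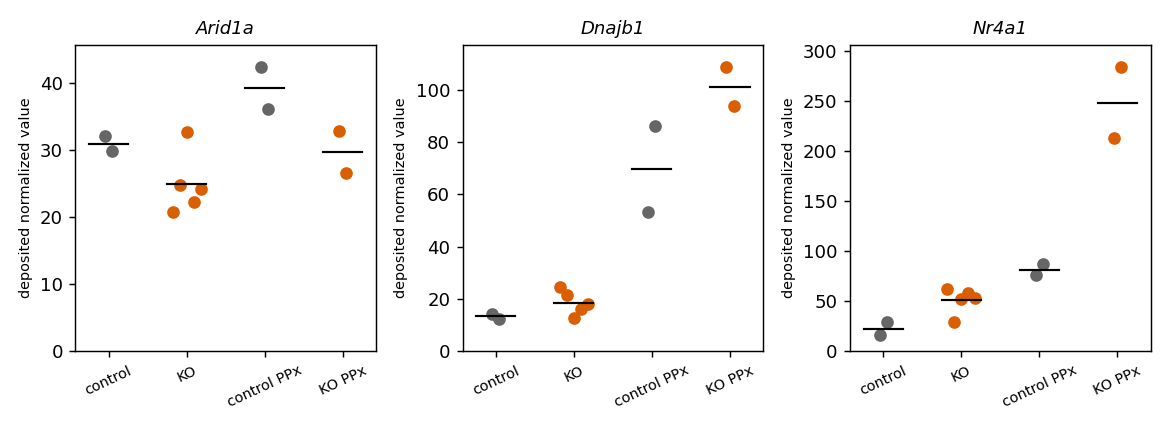
Deposited normalized values (linear axes from 0) of Arid1a, Dnajb1 and Nr4a1; each point is 1 library and each black line a group mean, by genotype and surgery. Arid1a overlaps between genotypes without PPx, while Dnajb1 is above 53 in all 4 libraries after PPx and below 25 in the other 7.

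The first comparison asked what Arid1a deletion changed without surgery. Immediate early genes, transcription factors and regulators induced rapidly by many stimuli, were higher as a list in KO islets, with a median log2 fold change of 0.74 over 11 members (camera, adjusted p = 1.54e-10). No member passed over all genes and 3 were higher when adjusted over the list alone; the list gave adjusted p = 0.356 with an estimated correlation. Their mean log2 level was 6.33 and 7.37 in the 2 controls and 7.17 to 7.81 in KO, and the size depended on 1 control: the median was 0.19 without control replicate 9 (adjusted p = 0.0481) and 1.27 without control replicate 11. Nr4a1, a nuclear receptor of this list, was 22.3 ± 9.08 (SD, n = 2) in control and 50.7 ± 13.0 (SD, n = 5) in KO. Beta cell genes did not pass, with a median of 0.07 over 27 members (adjusted p = 0.807), and Ins1 was 17070 ± 3441 (SD, n = 2) in control and 17020 ± 4621 (SD, n = 5) in KO. The smallest adjusted p of 0.392 was shared by Fam46a, 17.0 ± 0.489 (SD, n = 2) in control and 32.3 ± 0.863 (SD, n = 5) in KO, and Toporsos, which was listed at 0 in both controls and 3.72 to 7.95 in KO; Toporsos is an opposite-strand gene and strand use in the counting is not given, so its reads are uncertain. No gene passed in limma, and 323 had an unadjusted p under 0.05 where chance gives 737; leaving out control replicate 11 called 8, and control replicate 9, control PPx replicate 5 or control PPx replicate 6 called 1 each. The median log2 fold change of all genes was 0.12. The shared spread also draws on the KO libraries after PPx, which varied more (1.05 against 0.57 to 0.7 elsewhere). A fit of only the 2 groups compared had 577 genes with an unadjusted p under 0.05. A count below chance is therefore no evidence that nothing differed.

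The comparison of genotypes after PPx asked whether KO islets differed once tissue had been removed. Sdf2l1, an endoplasmic reticulum chaperone component, fell from 27.6 ± 3.80 (SD, n = 2) in control to 3.76 ± 1.39 (SD, n = 2) in KO, a log2 fold change of -2.79 ± 0.30 (SE, limma, adjusted p = 0.0014, and 0.0408 with library weights). The respiratory chain genes Cox6c, Ndufc1, Atp5e and Ndufa1 and the RNA polymerase subunit Polr2f were listed at 0 in both KO libraries; Cox6c was 45.0 and 20.4 and Polr2f 16.1 and 14.5 in the controls. Usmg5, Mir344c and Tspan8 were listed at 0 in both KO libraries as well. Usmg5 was 53.8 and 14.3, Mir344c 9.98 and 23.4 and Tspan8 3.62 and 4.16 in the controls. Whether transcript length explains these values at 0 was not tested gene by gene. Mir6984 and Mir6898, microRNA loci annotated inside Mrpl21 and Kansl3, whose reads may come from those genes, rose, with Mir6984 at 16.0 and 16.6 in KO against 0.069 and 0 in control. These genes also passed with library weights.

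Some genes passed the planned test but not the fit with library weights. Pcsk1, the prohormone convertase that processes proinsulin, was 138 ± 18.3 (SD, n = 2) in control and 28.1 ± 0.439 (SD, n = 2) in KO (log2 fold change -2.27, adjusted p = 0.0141 in limma, 0.121 with library weights). Insm1, an endocrine transcription factor, had -1.13 (0.0144 and 0.13), and Nr4a1 had 1.60 (0.0296 and 0.226). Ins1, Gcg and Sst did not pass: Ins1 was 18880 ± 6420 (SD, n = 2) in control and 3277 ± 677 (SD, n = 2) in KO, and Gcg 9034 ± 2606 (SD, n = 2) and 1397 ± 5.73 (SD, n = 2). Ins2 had a log2 fold change of -2.38 ± 2.75 (SE). This SE follows the variance trend of genes of like level more than the spread of Ins2 itself. The Ins2 share of the total was 27.3% and 20.8% in the controls and 6.44% and 6.59% in KO. Ins1, with an SE of 0.98, was tested with the same trend, so neither result shows that insulin genes did not differ. Of 27 beta cell list members, 8 were lower over all genes and 16 adjusted over the list alone, and of 20 unfolded protein response members 2 and 8 were; with median-of-ratios scaling 2 and 1 were lower over all genes. The lists gave adjusted p = 0.00896 and adjusted p = 0.00763 in camera, and adjusted p = 0.736 for both with an estimated correlation. With median-of-ratios scaling the beta cell list no longer passed (adjusted p = 0.328), nor did it without control PPx replicate 5 (median -0.79) or KO PPx replicate 8 (-0.64), and the unfolded protein response list did not pass without KO PPx replicate 7 (-0.60). Immediate early genes had a median of 0.67 (adjusted p = 1.57e-09, and adjusted p = 0.475 with an estimated correlation), which was 0.44 without KO PPx replicate 8. With median-of-ratios scaling their median was 1.18, with 6 members higher over all genes against 1 in the planned fit. Mitosis (median 0.22), ERK feedback targets (0.26), TGF-beta and YAP targets (0.41), cytokines (0.64) and the Reg family (0.28) also passed in camera against a median of all genes of -0.53, as did acinar (0.002), stellate (0.08) and macrophage markers (-0.004, mean 0.10). Each was lost with an estimated correlation, the smallest at adjusted p = 0.475. With median-of-ratios scaling 5 of the 11 lists passed, and mitosis (adjusted p = 0.109), Reg family (0.409), acinar (0.288), stellate (0.373) and macrophage genes (0.328) did not. Of the 11 lists, 3 passed without control PPx replicate 5 and 4 without KO PPx replicate 8. With library totals kept as deposited, the positive medians rested on KO PPx replicate 8: without it mitosis had -0.075, ERK feedback targets -0.315, TGF-beta and YAP targets -0.29 and cytokines 0.06. The mean log2 level in KO PPx replicate 7 was 1.45 for mitosis (1.51 and 1.67 in the controls) and 2.81 for TGF-beta and YAP targets (3.19 and 3.26). With median-of-ratios scaling it was 1.78 (1.46 and 1.71) and 3.34 (3.10 and 3.33), so its place against the controls depended on the scaling. EGF family ligands and ERBB receptors gave adjusted p = 0.163 over 8 tested members; the study is known to concern this pathway, so the list is not independent evidence.

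The planned limma fit called 1443 genes here, 41 higher and 1402 lower, but with library weights it called 55, 2 higher and 53 lower, and a fit of only these 4 libraries called none. In simulations with 200 of 14738 genes changed and the spread of the real libraries, where the KO libraries after PPx varied more than the rest, a mean of 134.4 of 263.6 calls of the planned fit were false (51%), against 5.4 of 109 with equal spread and 4.2 of 76.6 with library weights. These shares depend on how many genes are changed, so they show that the planned fit exceeded its false discovery rate there and are no estimate for the real calls. The share with library weights was built in, since the simulated spreads came from that fit's own model. The median log2 fold change of all genes was -0.53, and 235 of the lower genes were listed at 0 in both KO libraries; median-of-ratios scaling called 740, 140 higher and 600 lower. Leaving out single libraries gave between 103 and 4473 genes: 103 without control PPx replicate 5, 260 without control PPx replicate 6, 4473 without KO PPx replicate 8, and 862, 939, 763 and 785 without KO replicates 13, 14, 15 and 16.

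PPx in control islets addressed the response to surgery with Arid1a intact. Stellate cell and fibroblast genes were higher as a list, with a median log2 fold change of 1.58 over 15 members (camera, adjusted p = 1.09e-06), but the 2 libraries differed widely: Col1a1 was 2.08 and 59.1 after PPx. Interferon response genes had a median of 0.75 (adjusted p = 0.000131), endothelial genes 0.56 (6.32e-05), TGF-beta and YAP targets 0.61 (0.00144), SWI/SNF subunits 0.32 (4.63e-05) and immediate early genes 0.79 (1.77e-07). Acinar cell genes, digestive enzymes of the exocrine pancreas, had a median of -2.34 (2.82e-06). That value rests on 1 control library without PPx: Prss2 was 748 in replicate 11 and 12.3 in replicate 9, and without replicate 11 the acinar median was 0.35. None of these lists kept its call with an estimated correlation, where the smallest was adjusted p = 0.779. Without control PPx replicate 6, 4 of the 7 lists passed. Without control replicate 9, 5 passed: TGF-beta and YAP targets had 0.06 (adjusted p = 0.222) and immediate early genes 0.26 (adjusted p = 0.0502), and interferon response genes had 0.215, endothelial genes 0.33 and stellate genes 0.72. Much of the size of these rises therefore came from that library. Dnajb1, a heat shock co-chaperone, was 13.3 ± 1.29 (SD, n = 2) without and 69.8 ± 23.1 (SD, n = 2) after PPx (log2 fold change 2.33 ± 0.32 SE, limma, adjusted p = 0.228). No gene passed in limma, and 608 had an unadjusted p under 0.05 where chance gives 737. With only the 2 groups compared it was 594. The shared spread also draws on the KO libraries after PPx, which varied more, so this count is no evidence that nothing differed. Leaving out control PPx replicate 5 called 12, control replicate 11 called 5, and control replicate 9 or KO replicate 15 called 1 each.

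PPx in KO islets was compared with KO islets without surgery. Among beta cell genes, Insm1 fell from 81.1 ± 9.27 (SD, n = 5) to 24.2 ± 4.88 (SD, n = 2) and Pcsk1 from 174 ± 50.5 (SD, n = 5) to 28.1 ± 0.439 (SD, n = 2). Glp1r, the GLP-1 receptor, fell by 1.51 and Prlr, the prolactin receptor, fell by 1.59 on the log2 scale. The chaperones Sdf2l1, Pdia4, Hyou1 and Hsp90b1 had log2 fold changes of -3.34, -1.77, -1.61 and -1.41. Hypoxia and glycolysis members Ndrg1, Bnip3 and Aldoa had -1.99, -2.02 and -1.19, and the cyclin Ccnd2 -1.60. Nr4a1 rose from 50.7 ± 13.0 (SD, n = 5) to 248 ± 49.9 (SD, n = 2), with a log2 fold change of 2.32. All of these passed both fits: adjusted p in limma ran from 5.52e-05 for Sdf2l1 to 0.00266 for Bnip3, and with library weights from 0.00571 for Sdf2l1 to 0.0316 for Bnip3. Both fits kept the library totals as deposited, and the median log2 fold change of all genes was -0.70. Part of the falls may therefore be a difference in scale between libraries. Of 27 beta cell members 17 were lower and 1 higher in the planned fit, and 19 lower adjusted over the list alone; of 20 unfolded protein response members 16 and 17 were lower, with 1 higher adjusted over the list alone. With median-of-ratios scaling 9 beta cell members were lower and 2 higher, and 13 unfolded protein response members lower and 1 higher. Lower values were not particular to beta cells. Alpha cell genes had a median of -1.53 (10 of 10 negative, 6 lower), delta and PP cell genes -1.42 (6 of 6 negative, 3 lower) and acinar genes -2.59 (28 of 28 negative, 2 lower), against -1.10 for beta cell genes. These 3 lists did not pass (adjusted p = 0.134, 0.19 and 0.565), but acinar genes did with median-of-ratios scaling (0.0351). SWI/SNF subunits had a median of -0.30 with 1 higher and 6 lower and did not pass (camera, adjusted p = 0.0973). With median-of-ratios scaling they had 0.36 with 9 higher and 2 lower and passed (camera, adjusted p = 0.00201). Amy2a5, an acinar amylase, was listed at 0 in both libraries after PPx and 56.4 to 1973 without (adjusted p = 0.0141 in limma, 0.145 with library weights). Members of the hypoxia list were lower in 7 of 11 and the list did not pass (adjusted p = 0.12), but with median-of-ratios scaling it passed (adjusted p = 0.0372), with 7 lower and 1 higher. The beta cell and unfolded protein response lists had adjusted p = 0.0155 and adjusted p = 0.00134 in camera, and adjusted p = 0.656 for both with an estimated correlation. The beta cell list no longer passed with median-of-ratios scaling (adjusted p = 0.317) or without KO PPx replicate 8 (median -0.79). Stellate genes had a median of 1.46 (adjusted p = 8.15e-07, and adjusted p = 0.514 with an estimated correlation), but Col1a1 was 8.52 and 109 in the 2 libraries. Immediate early genes had a median of 0.88 (adjusted p = 3.23e-08) and mitosis genes 0.70 (adjusted p = 9.14e-05), with adjusted p = 0.514 and adjusted p = 0.189 with an estimated correlation. With median-of-ratios scaling these medians were 1.55 and 0.955. Then 11 and 2 members were higher over all genes, against 4 and 0 in the planned fit. TGF-beta and YAP targets (median 0.57), cytokines (0.89), ERK feedback targets (0.24) and endothelial genes (0.14) also passed, as did interferon response (-0.23), progenitor (-0.12) and macrophage genes (-0.23) with a camera direction up. Interferon response (adjusted p = 0.284), progenitor (0.425) and macrophage genes (0.317) did not pass with median-of-ratios scaling. All were lost with an estimated correlation, and without KO PPx replicate 8, 4 of 12 lists passed. Without that library TGF-beta and YAP targets had -0.05, ERK feedback targets -0.16, endothelial genes -0.85, stellate genes -0.45, cytokines 0.44, mitosis 0.05 and immediate early genes 0.51. In KO PPx replicate 7 the mean log2 levels of TGF-beta and YAP targets (2.81), cytokines (2.22), ERK feedback targets (3.56), mitosis (1.45) and stellate genes (1.64) lay within the range of the KO libraries without surgery. With median-of-ratios scaling, which divided this library by the smallest factor (0.612), all but stellate genes lay above that range: 3.34 for TGF-beta and YAP targets (2.68 to 3.13), 2.61 for cytokines (1.935 to 2.51), 4.23 for ERK feedback targets (3.29 to 3.57) and 1.78 for mitosis (1.14 to 1.34). Whether these lists were higher in both libraries therefore depended on the scaling.

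The planned fit called 5589 genes for PPx in KO, 414 higher and 5175 lower; library weights called 2049, 27 higher and 2022 lower. In the simulations with 200 genes changed and the real spread, a mean of 398 of 544.2 calls of the planned fit were false, which is no estimate for the 5589. The median log2 fold change was -0.70, and median-of-ratios scaling called 4189, 1657 higher and 2532 lower, and under it Arid1b turned from -0.06 to 0.60 and Arid1a moved from 0.26 to 0.93, which then passed (adjusted p = 0.0131 in limma). Without KO PPx replicate 7 the planned fit called 3534.

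The interaction asked whether PPx acted differently in the genotypes. Sdf2l1 had an interaction of -3.17 ± 0.39 on the log2 scale (SE, limma, adjusted p = 0.00584, 0.0537 with library weights), Glp1r -1.61 (0.0314 and 0.139) and Insm1 -1.42 (0.0356 and 0.127). The named genes that passed both fits were Mir6984, with 6.36 (0.00584 and 0.0426), and Cox6c, Ndufa4, Ndufc1, Snrpg and Atp5e, which were listed at 0 in both KO libraries after PPx and above 0 in the other 9. The planned fit called 325 genes, 5 higher and 320 lower, and library weights 29, 1 higher and 28 lower; in the simulations with 200 genes changed, a mean of 27.4 of 107 planned calls were false. The median interaction of all genes was -0.66, and median-of-ratios scaling called 107. The count was 38, 42 and 91 without control PPx replicate 5, control replicate 9 and control PPx replicate 6, and 97, 70, 87 and 82 without KO replicates 13 to 16. It was 849, 926 and 3947 without KO replicate 12, control replicate 11 and KO PPx replicate 8.

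Over both states, immediate early genes were again higher in KO, with a median log2 difference of 0.71 over 11 members, 9 of them adjusted over the list alone and none over all genes (camera, adjusted p = 3.62e-20, and adjusted p = 0.189 with an estimated correlation). Nr4a1, Nr4a2, Fosb and Klf2 were among the 5 smallest p of the higher genes, with log2 differences of 1.36, 2.00, 0.94 and 0.80 and adjusted p = 0.833 in limma. TGF-beta and YAP targets had a median of 0.37 (adjusted p = 3.07e-06), cytokines 0.58 (4.33e-05), acinar genes 0.56 (0.000165) and ERK feedback targets 0.27 (0.000706), with macrophage genes 0.125 (0.0407) and stellate genes 0.10 (0.0498), and all were lost with an estimated correlation, the smallest of these at adjusted p = 0.223. With median-of-ratios scaling macrophage (adjusted p = 0.127) and stellate genes (0.226) did not pass. The mean log2 level of acinar genes was 3.29 and 8.23 in the 2 controls without PPx, and the pooled acinar median was -0.64 without control replicate 9 and did not pass. It was 1.72 without control replicate 11, and without KO PPx replicate 7 it was 0.59 and did not pass. No gene passed in limma, and 739 had an unadjusted p under 0.05 where chance gives 737; leaving out KO replicate 14, KO replicate 15 or KO PPx replicate 7 called 1 each.

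Over both genotypes, Dnajb1 rose with PPx by a log2 difference of 2.41 ± 0.20 (SE, limma, adjusted p = 0.00149, 0.0429 with library weights), and it was the 1 gene that passed both fits. In camera 11 lists passed. Stellate genes had a median of 1.25 (adjusted p = 8.57e-10), immediate early genes 0.77 (8.42e-11), TGF-beta and YAP targets 0.50 (9.3e-07), endothelial genes 0.31 (0.000165), cytokines 0.63 (0.000618) and mitosis 0.35 (0.000811). ERK feedback targets had 0.10 (0.00162), interferon response genes 0.12 (0.0019), SWI/SNF subunits 0.04 (0.00337), unfolded protein response genes -0.975 (0.00267) and acinar genes -2.525 (0.00765). All were lost with an estimated correlation, the smallest at adjusted p = 0.307. Medians near 0 depended on the scaling. With median-of-ratios scaling ERK feedback targets had 0.48, interferon response genes 0.51 and SWI/SNF subunits 0.44. Of SWI/SNF subunits 8 were then higher and 1 lower over all genes, against 1 and 1 in the planned fit. For unfolded protein response genes the pooled value may average unlike genotypes, with -0.23 in control (adjusted p = 0.103, and 0.0376 with median-of-ratios scaling) and -1.57 in KO. Interferon response genes had 0.75 in control and -0.23 in KO, but their interaction did not pass (camera, adjusted p = 0.966). With median-of-ratios scaling their medians were 0.78 and 0.24. Acinar genes did not pass without control replicate 11 (-1.76), nor endothelial genes without KO PPx replicate 8 (-0.14). The inducible chaperones Hspa1a and Hspa1b, near-identical copies whose reads may be split, had 3.47 and 3.57 in the planned fit (adjusted p = 0.0224 and 0.028, and 0.17 and 0.206 with library weights). The planned fit called 2330 genes, 286 higher and 2044 lower, with a median of all genes of -0.43; median-of-ratios scaling called 936 higher and 1191 lower. In the simulations with 200 genes changed, a mean of 49.6 of 206.2 planned calls were false. The count fell to 43 without control replicate 11, 29, 33, 24 and 16 without KO replicates 13 to 16, 851 without control PPx replicate 6, and 22 and 6 without KO PPx replicates 7 and 8, and rose to 4859 and 3993 without control replicate 9 and control PPx replicate 5.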

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

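The finer matching, the bootstrap intervals, the test of oxidative phosphorylation genes and the permutation of immediate early genes were tests chosen after the results were seen. The bootstrap resampled genes and not mice, so its intervals do not cover the spread between mice. The percentiles among matched lists drew genes singly, as if independent, so they do not cover that spread either. The matching pool was not limited to protein-coding genes.

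The interaction test called 325 genes, 29 with library weights. It rests on the 2 KO libraries after PPx. A PPx effect that differs between genotypes therefore cannot be told from poor or scarce RNA in these libraries. Among named genes the interaction was 6.36 for Mir6984, 4.26 for Mir6898, 4.23 for Snora68, -1.23 for Gltscr1l, -1.61 for Glp1r, -1.42 for Insm1, -3.17 for Sdf2l1 and -3.08 for Usp18. Of these 8 genes, Mir6984 alone passed with library weights, and Snora68, Gltscr1l, Glp1r, Insm1 and Usp18 did not pass with median-of-ratios scaling. Among lists the median interaction was -1.14 for beta cell genes, 0.34 for mitosis, 0.09 for ERK feedback targets, -1.23 for the unfolded protein response, 0.01 for TGF-beta and YAP targets, -0.61 for acinar genes and 0.05 for immediate early genes, all lost with an estimated correlation; 1 of the 7 passed without control replicate 11 and 2 without control PPx replicate 5, and beta cell and acinar genes did not pass with median-of-ratios scaling. With median-of-ratios scaling the medians were -0.49 for beta cell genes, 0.66 for mitosis, 0.59 for ERK feedback targets and -0.64 for the unfolded protein response. They were 0.55 for TGF-beta and YAP targets, -0.14 for acinar genes and 0.69 for immediate early genes. In the planned fit the camera direction of acinar genes was up while their median and mean (-0.82) were negative, and that of TGF-beta and YAP targets was up with a mean of -0.10. A single library stood apart in 2 of 39 values tested among the KO libraries without PPx, where chance flags about 1 in 20: Erbb3 was 0.165 in replicate 13 against 0.503 to 0.578, and the mean log2 level of p53 targets was 3.58 in replicate 12 against 3.81 to 3.89.

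Most changed genes were lower in the KO libraries after PPx. Short transcripts as the whole cause are argued against by a difference of -0.35 between the shortest and the longest of 5 length bins (bootstrap 95% interval -0.41 to -0.29), although part of the shift does follow length. From the shortest to the longest bin the medians were -0.79, -0.67, -0.62, -0.54 and -0.44. These bins held only genes with higher values in the controls after PPx, 1162 or 1163 genes each. They therefore do not single out the very shortest transcripts. The highest of 5 bins of control values had a median of -0.57, but this cannot decide whether low values dropped out. Library totals were kept, so a lower total lowers high genes as well. Median-of-ratios scaling moved the median of all genes from -0.53 to -0.10. With that scaling 600 of 740 called genes were still lower. Oxidative phosphorylation genes drew attention through members listed at 0; the 45 members above 0 in both libraries and not named had a median of -0.91, at percentile 0.1 of random lists of such genes matched on length and level (median -0.55), and at 0.31 with the finer match. Poor or scarce RNA in these 2 libraries, and PPx in KO mice itself, stay open, since no design element separates them.

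Islet hormone and beta cell genes had lower values in the same libraries. Hormones lay at percentile 0.79 of matched lists, but at 2.57 with a finer match on length, so short transcripts stay open as a cause. Fewer endocrine cells also stay open: beta cell genes of at least 2 kb differed from matched genes by -0.13, with an interval of -0.47 to 0.43. No biological explanation could be separated from these.

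Immediate early genes had higher list medians in KO in both states, but the size depended on single libraries: 0.74 became 0.19 without control replicate 9, and 0.67 after PPx became 0.44 without KO PPx replicate 8. It also depended on the scaling. With median-of-ratios scaling the medians were 0.61 without PPx and 1.18 after PPx. This list was picked because it stood out among 26. Of all 126 splits of the libraries within each state, 16 gave at least 1 of the 26 lists a standardized difference as large as its 2.28 (two-sided exact permutation p = 0.127; highest other 2.56), so chance stays open. Handling stress stays open, since heat shock genes had a pooled median of 0.10. An effect of genotype is a hypothesis only.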

How the results depend on the processing

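The 2 settings on transcript length were chosen after seeing the data. Removing the length trend also took out each library's level, so it acted as a scaling as well. With transcripts of at least 2 kb alone, KO vs control after PPx gave 1404 genes. In simulations unequal spread between libraries inflated the counts for comparisons with the KO libraries after PPx; other causes were not tested. For KO vs control after PPx the count of 1443 became 740 with median-of-ratios scaling, 639 with quantile normalization, 55 with library weights, 508 with the length trend removed and 0 with only the 2 groups compared, and 103 to 4473 when single libraries were left out. For PPx in KO 5589 became 2049 with library weights and 3534 to 6691 without single libraries. Apart from library weights and KO PPx replicate 7 left out (3534), the total stayed within 1.5 times in the settings run. The genes called and their direction changed more, from 414 higher and 5175 lower in the planned fit. Median-of-ratios scaling gave 1657 higher and 2532 lower, quantile normalization 1918 and 2118, and the length trend removed 1765 and 2071. Calls shared with the planned fit were 2946 of 4189, 2532 of 4036 and 2467 of 3836. For the interaction 325 became 127 with a pseudocount of 4, 107 with median-of-ratios scaling, 89 with quantile normalization, 179 with no variance trend, 29 with library weights, 70 with the length trend removed and 38 to 3947. For PPx over both genotypes 2330 became 1260 with no variance trend, 1 with library weights and 6 to 4859. KO vs control without PPx gave 1 gene with only the 2 groups compared and 0 to 8 without single libraries, PPx in control 0 to 12, and KO over both states 0 to 1; where a left-out library leaves 1 in a group, it is assumed to vary like the rest. Arid1a in KO vs control did not pass in any setting run, from -0.42 to -0.26 without PPx and -0.55 to -0.25 after PPx over single libraries left out, but after PPx it was 0.11 with median-of-ratios scaling and 0.03 with the length trend removed.

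All list calls were lost with an estimated correlation. Arid1b with PPx in KO turned to 0.60 with median-of-ratios scaling and 0.53 with quantile normalization. Over single libraries left out, list medians for KO without PPx ran from -2.60 to 4.29 (Reg family, control replicates 9 and 11) and -1.92 to 3.41 (acinar, the same libraries), and without control replicates 9 and 11 acinar genes had -4.97 and 0.35 for PPx in control and 1.94 and -3.11 for the interaction. Without KO PPx replicate 8 they were -1.53 (stellate, after PPx), -1.42 (endothelial, after PPx), -0.85 (endothelial, PPx in KO), -0.73 (beta cell, interaction), -1.35 (endothelial, interaction) and -0.38 (stellate, KO over both states); without KO PPx replicate 7 the same lists had 1.79, 0.44, 0.83, 0.20 (endothelial, interaction) and 0.79, and beta cell genes had -1.32 for the interaction without control replicate 11. For the lists named here the camera direction turned in at least 1 of these settings; the cause was not tested. The planned edgeR and DESeq2 alternatives were not run, since whole reads were not recovered. Unknown depth limits what can be said of values at 0.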

Other observations

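Dpp4, a peptidase that cleaves incretin hormones, had log2 fold changes with PPx of -1.87 in control (limma, adjusted p = 0.228) and -1.52 in KO (adjusted p = 0.00198, 0.0534 with library weights). Over both genotypes it had -1.66 (adjusted p = 0.0115, 0.108 with library weights), so it passed the planned fit and not the weighted one. Nrg1 was too low to test, with a deposited value of 1.41 in KO PPx replicate 8 and at most 0.255 in the other libraries. Mki67, a proliferation marker, was 1.14 and 4.36 in the 2 KO libraries after PPx and 1.70 and 2.04 in the controls after PPx. In the simulations with the real spread, the weighted fit recovered 39.7% of genes changed by a log2 fold of 2 and 0.9% of those changed by 1 for KO vs control after PPx, so smaller differences between these groups were mostly not detectable.

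Other splits of the samples were drawn for the 2 pooled comparisons, 100 of 126 splits each. For KO vs control over both states the real split gave 0 genes, so all 100 splits gave at least as many by construction and the count says nothing about chance. The highest other split gave 2889, which points to a structure of the samples. It set control replicate 9, KO replicate 12 and both KO libraries after PPx against the rest. Control replicate 9 and KO replicate 12 had the lowest totals without PPx (355100 and 344216). For PPx over both genotypes 2 of 100 splits gave as many as the real 2330, the real one included. The other gave 4425 and set control replicate 9, control PPx replicate 6 and both KO libraries after PPx against the rest, so it kept 3 of the 4 libraries after PPx together and exchanged control PPx replicate 5 for control replicate 9. That split also held the libraries with the lower totals of each genotype, among controls 355100 and 345012 against 424872 and 409860. Both splits kept the 2 KO libraries after PPx together. The share therefore cannot tell an effect of PPx from 2 libraries unlike the rest. The count was 1 with library weights. The spread of the KO libraries after PPx may also affect the count (a mean of 49.6 of 206.2 calls false in simulations with 200 genes changed).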
